A study of Mus musculus with 2 samples.

How the data were processed

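Polyadenylated RNA from testes of day 10 mice was measured on 2 arrays, 1 from heterozygous (Mili+/-) and 1 from homozygous mutant (Mili-/-) animals, as the sample labels give them. The labels do not say how many mice stand behind each array. The probe set names and control names are those of a single-colour Affymetrix mouse array.

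The deposited values are linear signal intensities, 1 per probe set and array. From the values, the authors' table appears already scaled to a common level, because the mean without the lowest and highest 2% of probe sets was 99.98 on both arrays. The tool, its version and the background correction are not given in the sources used here, and no detection calls came with the values. The table held 12488 probe sets, of which 66 were control probe sets and were left out of all comparisons unless named. The Mili+/- array had 1 missing value, in a control probe set. Exact zeros occurred in 2 probe sets of the Mili+/- array and 1 of the Mili-/- array.

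Gene names came from a platform annotation table. Of the 12422 non-control probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had no row in the table and are unnamed here. Symbols were updated through the Entrez ID in a RefSeq gene table of assembly GRCm38.p6, which matched 10817 of the 10833 probe sets. No coordinates were used. No probe set was annotated to Piwil2, the gene that encodes MILI, so the genotype labels were not checked against the targeted transcript.

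Signals were floored at the 20th percentile of each array (6.3 for Mili+/- and 7.0 for Mili-/-), put on the log2 scale and centred on each array's median. Centring removed a shift of 0.11 (log2, higher in Mili-/-) between the deposited medians, and all differences are given after it as Mili-/- minus Mili+/-. A gene took the probe set with the highest mean signal among those with exactly 1 symbol, which gave 8251 genes. A gene was compared only if its brighter array reached the median signal of that array (38.5 for Mili+/- and 41.5 for Mili-/-), which left 5095 genes. Their median difference was -0.13, since at the 75th percentile the deposited signals were shifted by -0.027, against 0.11 at the median. The filter, the floor, the gene lists, the fold threshold of 2 and the rule for named genes were fixed before the data were examined.

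Each genotype had 1 array, so no test across replicates was possible and no p-value is given. Differences describe these 2 arrays. The only error that could be estimated was the disagreement between probe sets of the same gene. Over 720 genes with more than 1 probe set past the filter (1533 probe sets), its SD was 0.31 on the log2 scale. That figure covers neither differences between animals nor between hybridisations. The precision is limited by the number of arrays.

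For 18 lists written beforehand, the median difference of the members past the filter was set against 10000 random lists of the same size, matched on mean signal in 20 bins. A list was said to stand apart when its median lay under the 2.5th or over the 97.5th percentile of these random lists. This describes the position of the list on these arrays and is not a p-value. The retroelement list was defined by a pattern on gene names and picked only Iapp, the islet amyloid polypeptide gene, which was dim on both arrays and is no retroelement. The epididymis and adnexa list had 6 measured genes and none past the filter. These lists therefore gave no value, and 16 remained.

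Named genes were the 12 with the highest and the 12 with the lowest difference among genes past the filter, and from each list the up to 4 members with the largest absolute difference. Piwil2 was to be named as the target. Any other gene or probe set named was chosen after its values were seen.

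The code was tested on simulated data for this comparison, with signals drawn around the real means and a spread per brightness bin taken from the middle of the real differences. Of 50 genes raised 4-fold and 50 lowered 4-fold, 100% were found past the 2-fold threshold. Of 50 genes raised 2-fold 56% passed, and of 50 lowered 2-fold 54% passed, since their true change lay on the threshold. Among 4884 unchanged simulated genes, 24 passed it. A simulated list of 20 genes lowered by 0.4 was found at a median of -0.42.

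The alternatives were no centring, quantile normalization and loess on brightness (span 0.4), no floor and a floor at the 40th percentile, no filter and a filter at the 75th percentile, the mean over a gene's probe sets, leaving out probe sets whose suffix marks shared sequence or relaxed probe selection, fold thresholds of 1.5 and 3, and random lists without matching. The mean over a gene's probe sets also took in probe sets that did not pass the brightness filter. For lists, 3 of the 10 settings (no centring and both changes of floor) moved no percentile and bear on no list. A filter that both arrays had to pass was added after the data were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.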

Results

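The series compared gene expression in testes of homozygous mutant (Mili-/-) mice with that of heterozygous (Mili+/-) mice at day 10 after birth. MILI, encoded by Piwil2, is a germline Piwi protein that binds piRNAs. Per the labels, meiosis stops early in prophase in the mutant, and the submitters chose day 10 because dying cells were seen from day 11, to avoid differences that follow from cell loss. At this age the tubules hold Sertoli cells, spermatogonia and the first meiotic cells. Polyadenylated RNA of each genotype was hybridised to 1 array, so no value has a replicate.

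The 2 arrays were closely alike, with a Pearson correlation of 0.98 between their log2 signals across probe sets. Among the 5095 genes past the brightness filter, the central 95% of differences lay between -0.69 and 0.58 on the log2 scale. No probe set was annotated to Piwil2, so no value is given for the targeted transcript. The ratio of 3' to 5' control probe sets, a measure of RNA integrity, was 1.53 in Mili+/- and 1.52 in Mili-/- for Actb, and 1.001 and 1.008 for Gapdh. For 18S ribosomal RNA the ratio was 7.94 in Mili+/- and 5.42 in Mili-/-. This ratio is not read as integrity, since polyadenylated RNA was hybridised.

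The largest increases among bright probe sets were in 5 probe sets that the platform annotation assigns to several genes each, Noct among them for all 5, so no gene is named as their source. They took ranks 1 to 5 by increase among the 3319 non-control probe sets at or above the 75th percentile on either array. The one with the largest difference had a signal of 81.3 in Mili+/- and 549 in Mili-/-, 6.26-fold higher after centring. The brightest went from 670 to 2452 (3.39-fold), and the others from 534 to 1984 (3.44-fold), from 437 to 1526 (3.23-fold) and from 43.6 to 165 (3.51-fold). Those with Mili+/- signals of 81.3 and 43.6 reached the 75th percentile on the Mili-/- array alone, which favours higher values. A probe set assigned to Noct alone had signals of 158 and 168.5 (log2 difference -0.02). A further one, whose suffix marks shared sequence, had 287 and 395 (0.35). These probe sets were singled out after their values were seen. Their smallest log2 difference, 1.69, was larger than the SD of 0.31 between probe sets of one gene, and no replicate array tests it.

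**Figure D1:**
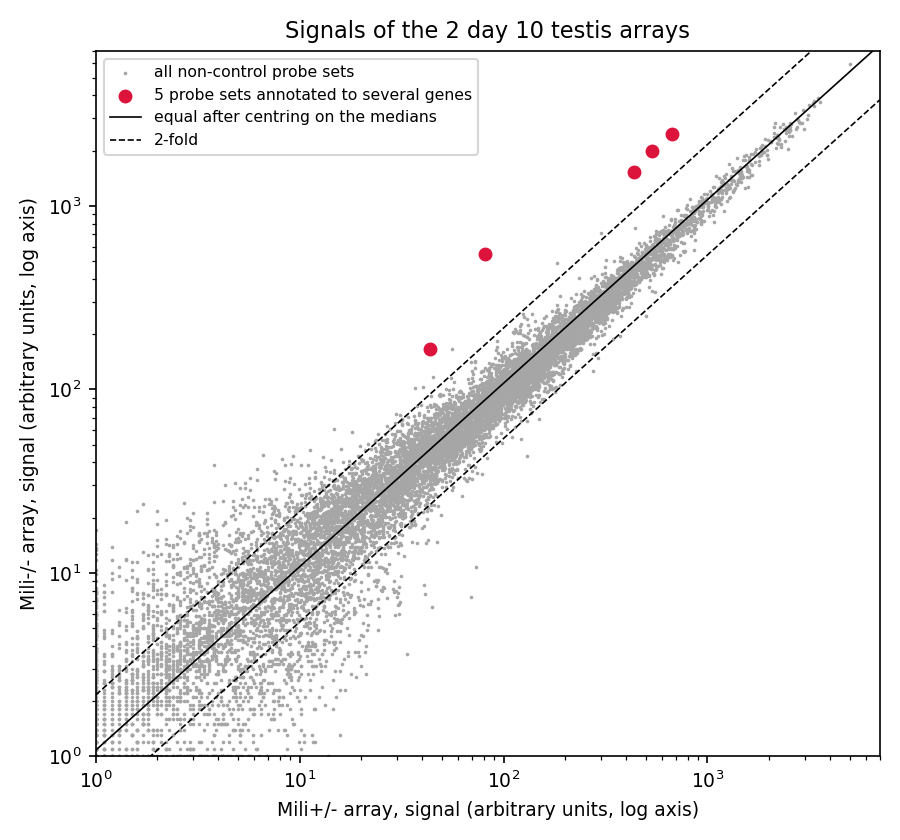
Signal of each non-control probe set in the Mili+/- array (horizontal, log axis, arbitrary units) against the Mili-/- array (vertical, log axis), with signals under 1 drawn at 1. The solid line marks equality after centring, the dashed lines a 2-fold difference, and the 5 red points are the probe sets assigned to several genes, which lie 3.23-fold to 6.26-fold above equality.

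Of single genes, 16 were at least 2-fold higher and 27 at least 2-fold lower in the Mili-/- array. The split depended on scaling. It was 30 higher and 17 lower with the values as deposited, 24 and 24 after quantile normalization, and 25 and 23 after loess. The highest was Cyp2e1, a cytochrome P450 that oxidises ethanol in the liver, with signals of 6.6 and 43.6 (6.12-fold). Next came the serotonin receptor gene Htr1b (4.74-fold), Strn4, which encodes a striatin scaffold protein (4.30-fold), and the Wnt ligand gene Wnt5b (2.99-fold). The others among the 12 highest were Zfp94, Car3, H3c14, Eya2, Pla2g4f, Otog, Rgs19 and Htr1d, between 2.72-fold and 2.09-fold. Car3 encodes a carbonic anhydrase abundant in fat and muscle, and H3c14 a histone H3 read by a probe set whose suffix marks relaxed probe selection. The signals of Cyp2e1, Htr1b and Strn4 in Mili+/- lay near the floor of 6.3, and with the floor at the 40th percentile their log2 differences were 0.84, 0.78 and 0.83, under 2-fold. For Rgs19 a further probe set went the other way (-0.35), and with the mean over probe sets Rgs19 (0.26) and Zfp94 (0.71) were under 2-fold.

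The lowest was Zbtb17, which encodes the Myc partner Miz-1, with signals of 73.3 and 10.8 (7.33-fold lower). Tanc1, whose Mili-/- signal of 6.5 lay under the floor of 7, was 6.89-fold lower with that floor, the Notch ligand gene Jag2 5.79-fold, the kinase gene Mast3 5.11-fold and Rps6kb2, which encodes a ribosomal S6 kinase, 3.46-fold. The Mili-/- signals of Jag2 (7.7) and Mast3 (8.6) also lay near the floor of 7. Bhmt, Ngdn, the myogenic factor gene Myog, Pgs1, Pcp2, the phosphodiesterase gene Pde7a and B230308N11Rik completed the 12 lowest, between 3.07-fold and 2.34-fold lower. With the floor at the 40th percentile, Zbtb17 stood at -1.67 and Rps6kb2 at -1.03, and Tanc1 (-0.96), Jag2 (-0.85), Mast3 (-0.83), Bhmt (-0.85), Ngdn (-0.88), Pgs1 (-0.80) and Pcp2 (-0.83) were under 2-fold. With the mean over probe sets Tanc1 stood at -1.43, and Bhmt (-0.57) and Pcp2 (-0.37) were under 2-fold. Of the 43 genes past 2-fold, 36 (83.7%) lay under the 75th percentile of signal on both arrays, against 45.3% of all genes past the filter. Only 1 of the 43 had a further probe set past the filter, Rgs19, and it did not share the direction. With both arrays required to pass the filter, a setting added after the data were seen, 2 genes were 2-fold higher and 6 lower, and 3 of the 24 genes named here remained. Among the 4884 unchanged genes of the simulated data, 24 passed 2-fold. Their noise was normal, with a spread taken from the middle of the differences on these same arrays, so 24 is no expected count for the tails.

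Spermatogonial genes were lower in the Mili-/- array. The median of the 17 members past the filter was -0.33 against -0.12 for matched random lists, a 1.15-fold lower level. The list stood at percentile 0.14, and 15 of 17 members lay below the random median. Sall4, a transcription factor of undifferentiated spermatogonia, had signals of 57.4 and 34.7 (-0.84). Stra8, induced by retinoic acid at meiotic entry, had 303 and 198 (-0.72). The receptor gene Kit of differentiating spermatogonia had 205 and 144 (-0.62), and the cyclin gene Ccnd1 had 118 and 84.3 (-0.60), with a second probe set at -0.65. No member reached 2-fold. Of its members, 2 passed the filter through the Mili+/- array alone, Sall4 among them, which favours lower values. With both arrays required to pass, the median was -0.31 (percentile 0.54).

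Genes of early meiotic prophase showed a median of -0.30 over 11 members, against -0.15 in random lists, and stood inside the random range at percentile 4.32. It lay outside that range without the brightness filter (percentile 1.53) and with the filter at the 75th percentile (0.49). The lowest members were Syce2, which encodes a central element protein of the synaptonemal complex (178 and 125, -0.62), and the DNA damage kinase gene Atm (168 and 119, -0.61). The cohesin gene Smc3 stood at -0.50 and Rad51ap1 at -0.45. Genes of pachytene cells and spermatids, stages that are still absent or rare at this age, had a median of -0.10 over 11 members and stood at percentile 52.1. Adam3 (0.61), Clgn (0.48), Odf1 (-0.37) and Hspa2 (-0.34) went both ways, and a second probe set of Clgn stood at 0.00. Odf1 passed the filter through the Mili+/- array alone.

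Only 5 of the 25 piRNA pathway genes had a probe set with 1 symbol, and 4 passed the filter. Their median was -0.50 against -0.10 in random lists, at percentile 0.27. The RNA helicase gene Ddx25 had signals of 134 and 95.6 (-0.60) and a second probe set at -0.71. The DNA methyltransferase gene Dnmt3a stood at -0.60 (-0.28 with the mean over its probe sets) and the chaperone gene Hsp90aa1 at -0.40. Ddx4, the mouse Vasa gene, had 246 and 244 (-0.12), close to the random median. The list value describes these 4 genes and not the pathway's other genes, which had no value here. The list no longer stood apart with the stricter filter (percentile 9.94) or the mean over probe sets (11.5). That mean took in dim probe sets, since no other probe set of Dnmt3a or Hsp90aa1 passed the filter. Dnmt3a passed the filter through the Mili+/- array alone, and with both arrays required to pass the median was -0.40 (percentile 2.32).

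Sertoli cell genes stood higher relative to genes of like brightness. The median of 29 members was 0.02 against -0.10 in random lists, at percentile 99.7, a 1.09-fold higher level. Of the members, 19 lay above and 9 below the random median. Amh, the anti-Müllerian hormone gene of immature Sertoli cells, had signals of 61.6 and 96.5 (0.54). Shbg (182 and 272, 0.47) and the homeobox gene Rhox5 (185 and 275, 0.47) were also higher, while Hsd17b1 was lower (57.7 and 45.5, -0.45). Leydig cell genes did not stand apart (13 members, median -0.16, percentile 23.4). Among them the steroidogenic genes Cyp17a1 (-0.37) and Hsd3b1 (-0.36) and the gene Thbs2 (-0.36) were at the low end and Igf1 (0.42) at the high end. A second probe set stood at -0.16 for Hsd3b1 and at 0.14 for Igf1. Genes of peritubular and stromal cells stood inside the random range (22 members, median -0.02, percentile 93.9), with Actg2 at 0.64, Fn1 at 0.36, Pdlim3 at -0.29 and the smooth muscle myosin gene Myh11 at -0.43. The suffix of the Actg2 probe set marks shared sequence.

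**Figure D2:**
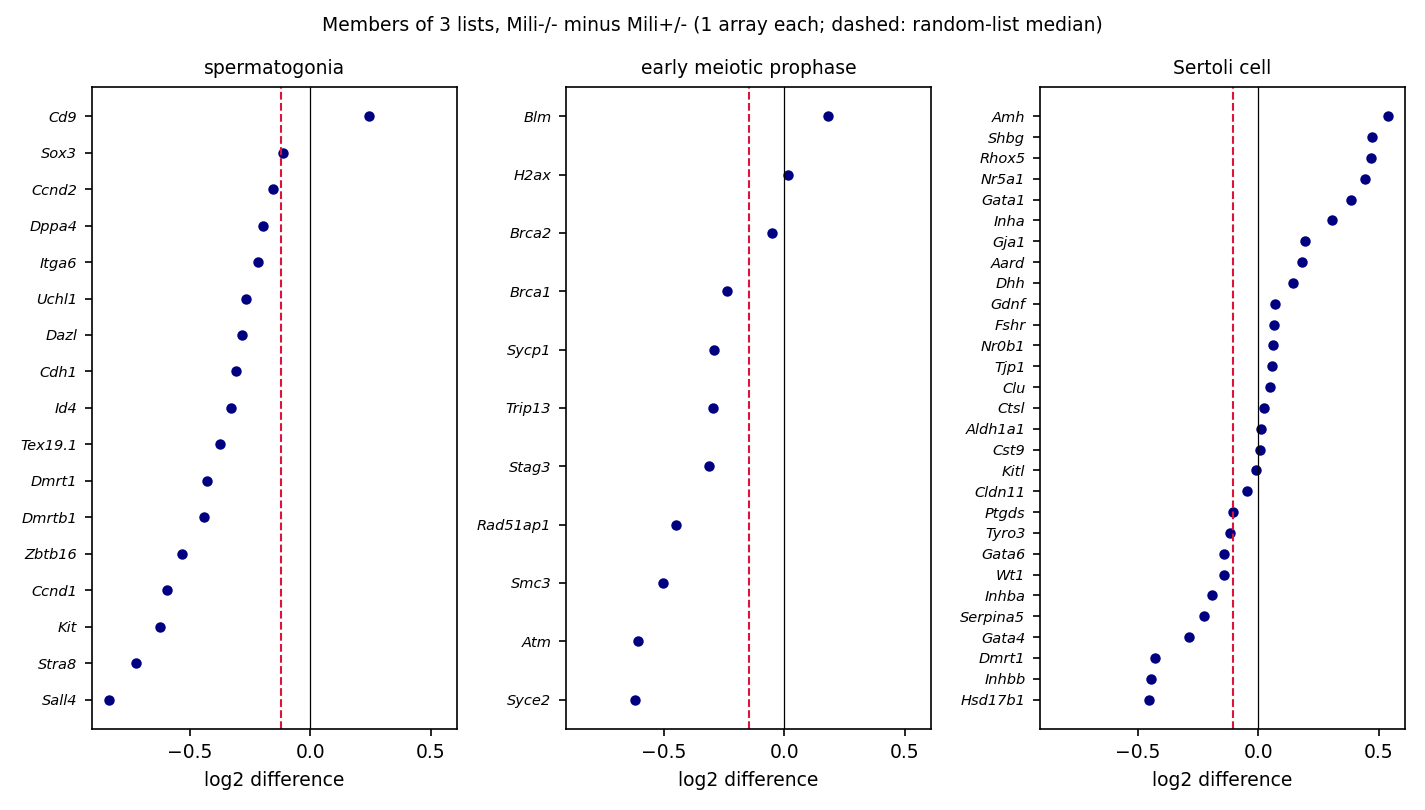
Each point is 1 gene past the brightness filter of the spermatogonia, early meiotic prophase or Sertoli cell list, placed by its log2 difference, Mili-/- minus Mili+/-, with 1 array per genotype and no error bars. The dashed line is the median of matched random lists, below which 15 of 17 spermatogonial genes lie and above which 19 of 29 Sertoli cell genes lie.

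Genes of other cell types that a testis sample can hold also differed. The 7 adipose genes past the filter had a median of 0.64, above every one of the 10000 random lists, with Car3 (36.7 and 101, 1.36), the desaturase gene Scd1 (69.1 and 140, 0.91, or 0.44 with the mean over its probe sets), the adipokine gene Adipoq (26.2 and 52.7, 0.90) and the fatty acid binding protein gene Fabp4 (33.9 and 56.9, 0.64). No other probe set of Scd1 passed the filter. Of the 7 adipose genes, 3 passed the filter through the Mili-/- array alone, which favours higher values. The median was 0.37 (percentile 99.9) with both arrays required to pass and 0.44 without the filter. The 6 erythroid genes past the filter had a median of 0.53, also above all random lists, and 2 of them, Alas2 and Rhd, passed through the Mili-/- array alone. The size of this difference depended on the members. The median was 0.17 without the filter (percentile 98.3), 0.17 with the stricter filter (percentile 99.1) and 0.22 with both arrays required to pass (percentile 99.6). It was 0.28 without probe sets of shared sequence or relaxed probe selection, and 0.28 to 0.77 when 1 gene was left out. Tspo2 stood at 0.95, the haem synthesis gene Alas2 at 0.82 and the blood group gene Rhd at 0.77, and the globin gene Hba-a1, at 1397 and 1828, stood at 0.28. Macrophage genes had a median of 0.10 over 13 members at percentile 98.5, with Cx3cr1 (0.68), Mpeg1 (0.57) and Cd74 (0.49) high and the lysozyme gene Lyz2 (-0.44) low. The list no longer stood apart under 6 of the 7 other settings that could move its percentile, and without 1 of its genes its percentile ranged from 93.1 to 98.7. The 6 endothelial genes stood inside the random range at percentile 94.6, with Mcam at -0.60, Pecam1 and Cdh5 at 0.45 and Eng at -0.25. Cx3cr1 and Pecam1 passed the filter through the Mili-/- array alone.

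Genes of apoptosis and of the p53 response stood inside the random range, with a median of -0.01 over 27 members at percentile 96.1. Casp9 had the largest difference (72.0 and 42.4, -0.87), but its other probe sets stood at -0.07 and -0.14. Bad (0.54, with a second probe set at 0.33), the p53 target gene Zmat3 (0.47) and Bid (-0.37) followed. Cell cycle genes had a median of -0.16 over 33 members at percentile 31.0. The primase gene Prim1 (59.6 and 33.0, -0.96), Mki67 (196 and 129, -0.71), Aurka (-0.50) and the replication gene Cdc45 (-0.48) were its lowest members. With the mean over its probe sets Mki67 stood at -0.17, but no other probe set of Mki67 passed the brightness filter. The interferon response list stood at percentile 46.8, with Irf7 at 0.83 and Tap1 (-0.70), Gbp3 (-0.41) and Irf1 (-0.37) below 0. Immediate early and heat shock genes stood at percentile 53.4, with Ddit3 at 0.67, Fos at -0.38, Fosb at -0.32 and Hspa1a at -0.31. Fos stood at 0.08 with the mean over its probe sets, of which no other passed the filter. Irf7, read by a probe set whose suffix marks shared sequence, and Ddit3 passed the filter through the Mili-/- array alone, which favours higher values. Prim1, Tap1 and Fos passed through the Mili+/- array alone, which favours lower values. Housekeeping genes stood at percentile 76.0, with Actb (-0.30, and -0.19 in a second probe set), Gusb (-0.27), Rpl13a (-0.26) and Tfrc (-0.24) at the low end. As deposited, without the centring that removed 0.11, the Actb control probe sets stood at 0.13 to 0.26.

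Of the 16 lists with a value, 6 stood apart, 4 higher and 2 lower, where 0.8 would fall outside the central 95% range by chance. Genes of a list are not independent replicates, and with 1 array per genotype these positions cannot be assigned to genotype rather than to the animals or the hybridisation.

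**Figure D3:**
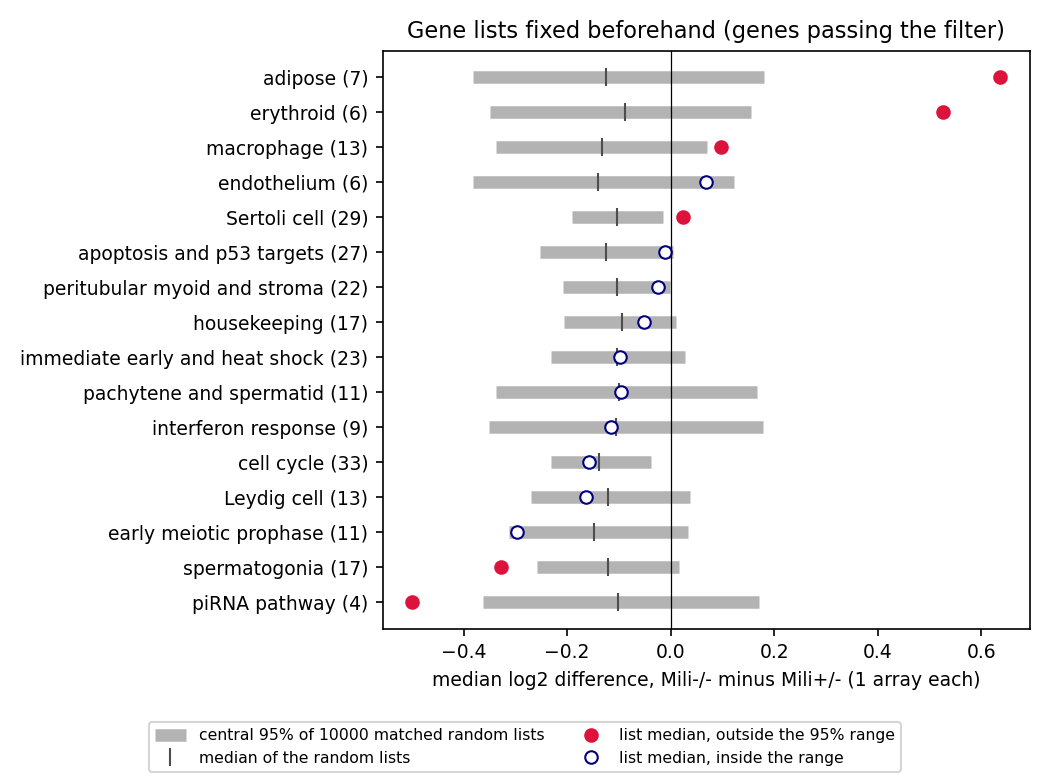
Median log2 difference, Mili-/- minus Mili+/-, of each list (circles, number of genes in brackets), with grey bars for the central 95% of 10000 random lists matched on signal and a tick at their median. Filled red circles lie outside the bar, from the piRNA pathway list at -0.50 to the adipose list at 0.64.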

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

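The tests of the probe sets assigned to several genes and of the spermatogonia and Sertoli cell lists were chosen after the results had been seen. The second adipocyte and erythroid lists were written before their medians were computed, but after the values of Cyp2e1, Cat and Tfrc had been seen, and how their medians were read was revised after they were known.

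Probe sets with several genes or no gene name stayed outside the gene-level comparison, and 12 of those past the filter were at least 2-fold higher in the Mili-/- array than in the Mili+/- control (5 were as much lower). The log2 differences of the 5 that share an annotation including Noct were 2.65, 1.81, 1.78, 1.76 and 1.69.

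A change of Noct itself is argued against by the probe set assigned to it alone without a suffix for shared sequence. It stood at -0.017, more than 2 SD between probe sets of one gene (0.62) below the lowest of these 5. Others assigned to Noct alone, with that suffix, stood at 0.35 and at -0.74, the latter dim (10.8 and 5.1). A general rise of probe sets whose suffix marks shared sequence is argued against too. The other 494 past the filter had a median of -0.063, against -0.13 for genes past the filter. The upper end of their central 95% range was 0.71, which decides little, since the 5 were singled out for their large increases. Transcripts of an interspersed repeat family may be the source, since MILI is known to silence such elements in germ cells, but this was not tested, because the annotation used here holds gene symbols only and no probe sequences were used. A difference between animals and an effect of genotype also stay open, which 1 array each cannot test.

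The spermatogonia list was lower and the Sertoli cell list higher. A trend of the differences with brightness is argued against as the whole cause, since the spermatogonia list stood at percentile 0.54 of random lists without matching on signal and 0.14 with it, and the Sertoli list at 99.4 and 99.7. A lower share of germ cells in the mutant testis could give both and would raise the other somatic lists alike, and over matched random lists the Sertoli list was higher by 0.13, peritubular by 0.08, macrophage by 0.23 and endothelium by 0.21, while Leydig stood at -0.04. The gap of 0.172 between Sertoli and Leydig lay at the edge of the central 95% range of random pairs (-0.182 to 0.173) and was 0.08 to 0.19 under other settings, and of the 10 pairs of these 5 lists 1 lay outside its range (Leydig minus macrophage, -0.28 against -0.25 to 0.26), so this explanation and a change of expression within germ cells cannot be told apart. An effect of genotype was not tested with 1 array each.

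The adipose and erythroid lists lay 0.76 and 0.61 above matched random lists, and fat or blood in the sample might bring such RNA. A second list of adipocyte genes (18 genes, Gpd1 at 0.58 and Plin2 at 0.47 among them) had a median of 0.077 at percentile 99.2, or 0.07 at percentile 99.1 without Cyp2e1, and a second list of erythroid genes (12 genes) had -0.096 at percentile 61.7. The second erythroid list lay inside the random range and below the first (0.53) by more than the bound set beforehand (0.17). It does not decide on blood, since members such as Prdx2 (1146), Alad (577.5) and Tfrc (332, also on the housekeeping list) were bright in the Mili+/- array. If other testis cells express them, more blood RNA would hardly move them. Of the 12 members, 7 lay above the random median, Ank1 (0.58) among them. The globin genes of the first list, Hba-a1 and Hbb-b2, stood at 0.28 and 0.165. For fat the second list met both bounds set beforehand, standing above the random range and yet below the first list (0.64) by more than 0.155, so these values do not decide that source. Genotype was not tested.

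Of the other probe sets outside the gene-level comparison, one assigned to 9 genes stood at 1.94 (signals of 11.3 and 46.7). Unnamed probe sets stood at 1.95, 1.62, 1.47, 1.24, 1.20 and 1.14, the last with signals of 300 and 713, and the 5 lower ones, unnamed too, at -1.70 (130 and 43.3), -1.36, -1.15, -1.12 and -1.05. Those at 1.95, 1.94, 1.62, 1.47 and 1.20 passed the filter through the Mili-/- array alone, which favours higher values. Those at -1.36, -1.15 and -1.12 passed through the Mili+/- array alone, which favours lower values. Among control probe sets, the one for the 5' part of 18S ribosomal RNA was higher by 0.49 as deposited (182 and 256), above the largest absolute difference of the 9 spike-in probe sets (0.43), while those for the middle and 3' part stood at -0.16 and -0.06.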

How the results depend on the processing

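Genes at least 2-fold higher numbered 16, and 30 with the values as deposited and 25 after loess. They numbered 157 without the brightness filter, 2 with the filter at the 75th percentile and 2 with both arrays required to pass the filter. Without probe sets of shared sequence or relaxed probe selection they numbered 10, at a threshold of 1.5-fold 126 and at 3-fold 3. Genes at least 2-fold lower numbered 27, and 17 as deposited, 16 with the floor at the 40th percentile, 148 without the filter, 5 with the stricter filter, 6 with both arrays required to pass, 257 at 1.5-fold and 7 at 3-fold. Thresholds and filters change the counts by construction, and the cause of the scaling changes was not tested beyond the median shift of 0.11. The spermatogonia, Sertoli cell, adipose and erythroid lists stood apart in the same direction under the 7 settings that could move a percentile. No centring and both floors moved none. These lists did too with both arrays required to pass, chosen after seeing the data. Sublists without genes of other testis cells (spermatogonia -0.38, Sertoli 0.06) were picked after seeing values and decide nothing. The piRNA pathway list came inside the random range at -0.26 with the stricter filter and at -0.24 with the mean over probe sets, dim ones included. The early meiotic list lay outside it at -0.30 without the filter and -0.38 with the stricter one, and the apoptosis list at 0.12 after loess. The macrophage list lost its position under 6 of these 7 settings and with both arrays required to pass, and the endothelial list gained one without the filter. None of the 6 lists that stood apart came to lie on the other side of its random median, while 5 others did, the apoptosis (percentiles 42.9 to 97.7), Leydig (14.1 to 71.1), pachytene (14.7 to 80.5), interferon (10.4 to 59.4) and immediate early (22.5 to 67.5) lists. The size was less stable than the call for the erythroid list, from 0.53 to 0.17 without the filter and 0.17 with the stricter one, and for the adipose list, from 0.64 to 0.44 without the filter. The 5 probe sets that share an annotation stayed between 1.69 and 2.79 under all scalings and floors. Of 767 values of the 87 named genes under alternatives, 24 moved by more than 0.31. These counts do not measure stability, since changes of filter leave a gene's value as it was and no centring shifts every gene by 0.11. Genes that a setting removed were not counted under it. Of the 24 highest and lowest genes none changed sign. With the floor at the 40th percentile 10 were no longer past 2-fold, and 4 with the mean over probe sets. Leaving out probe sets of shared sequence or relaxed probe selection removed 6, all read by probe sets of relaxed selection, so their folds were not tested there. With the stricter filter and with both arrays required to pass, 3 remained. Piwil2 and the retroelement list had no value under any setting. No paired analysis was possible because each genotype had 1 array, which also rules out leaving out a replicate. Signals carry no detection calls, so genes near the floor have uncertain folds.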

Other observations

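Among genes at or above the 75th percentile of signal on either array, 7 passed 2-fold, and they were chosen after their values were seen. Lower in the Mili-/- array were the chromatin protein gene Dek (500 and 251, 2.15-fold), Ccdc6 (273 and 126, 2.34-fold), the retromer subunit gene Vps26b (290 and 148, 2.11-fold), B230308N11Rik (150 and 69.2, 2.34-fold) and a probe set named for Mir686 (371 and 196, 2.04-fold). Higher were H3c14 (182 and 488, 2.49-fold) and Zfp94 (56.1 and 165, 2.72-fold), both from probe sets whose suffix marks relaxed probe selection. With the mean over its probe sets Zfp94 stood at 0.71, under 2-fold, though no other probe set of Zfp94 passed the brightness filter. No replicate array tests these values.

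Control probe sets for the short interspersed repeats B1 and B2 were read as deposited, where the median of all probe sets was 0.11 (log2) higher in Mili-/-. The B1 probe set had signals of 3503 and 3976 (1.14-fold), and the 2 probe sets for B2 had 3358 and 4168 (1.24-fold) and 362 and 340 (0.94-fold). The Actb control probe sets stood at 1.09-fold to 1.20-fold and the Gapdh ones at 1.08-fold to 1.11-fold, a range that held B1 but neither probe set for B2.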
